A study of Homo sapiens with 9 samples.

How the data were processed

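RNA was measured in 9 cultures of HepG2.2.15 cells, a hepatoma line derived from HepG2 that carries and releases hepatitis B virus. Per the labels, the cells had been kept for 48 h in medium with Suduxing, a traditional Chinese medicine preparation, at 0, 0.001 or 0.01 µg/ml, in 3 independent experiments per dose. The labels do not say what the preparation contains. Total RNA was copied into Cy3-labelled cRNA and each sample was hybridized to its own 1-colour Agilent array. The titles number the replicates 8, 9 and 11 at every dose, and these numbers are used here as replicate numbers.

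Each deposited array file holds spot intensity values, in arbitrary units, that the authors extracted with Agilent Feature Extraction 10.7.1.1. Per the file headers, the processed signal intensity is background-subtracted and detrended within each array, and it was not normalized between arrays. The files also give raw mean signals and local backgrounds as intensity. The deposited series table holds log2 values. All 9 of its columns hold the same sorted values to within 0.000654, so it was quantile-normalized between arrays, by a tool that is not named. The table was used only as an alternative. Each array had 58717 spots other than controls, for 42405 probes. The 75th percentile of the processed signal ran from 545 to 1730 between arrays, and 54.1% to 61.1% of spots were well above background by the extraction software's own call. No spot was saturated (0 on each array). With 3 arrays per dose, the number of arrays limits the precision of every value. The array identifiers place 8 arrays on 1 slide, while untreated replicate 11 was on another slide.

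The log2 of the processed signal was taken, and the 75th percentile of each array was subtracted. Spots with a non-uniformity or population outlier mark were left out, and the spots of a probe were averaged. Probes well above background on all 3 arrays of at least 1 dose were kept. Gene symbols came from matching the probes' RefSeq accessions, without version, to the reference gene table, which gave a symbol to 24826 probes. A gene with several kept probes was represented by the probe with the highest mean over the 9 arrays. This left 18080 transcripts for the tests, of which 12529 had a gene symbol and 5551 stood for a probe without one. They are called genes here. No genome build is given in the files, so no coordinates are reported. A gene not well above background on any array of 1 dose has no measured level there, and its change is given as "at least" a fold. That fold sets the mean of the other dose against the dim dose. On each array of the dim dose, the higher of the lowest signal among probes well above background and the gene's own signal was taken. The bound allows for this floor only, not for the spread between arrays or the choice of background correction.

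The choices below were made before the data were examined. The linear model of limma 3.58.1 in R 4.3.3 was fitted to all 9 arrays with a term per dose and no other covariate, and its empirical Bayes step gave 2-sided moderated tests with 6 residual degrees of freedom. P values were adjusted over all genes by the method of Benjamini and Hochberg, and a gene was called changed at an adjusted p under 0.05. The comparisons were 0.01 µg/ml against untreated, 0.001 µg/ml against untreated, the difference between both doses, and a moderated F-test over the 3 doses. Errors of log2 changes are standard errors of the model. Of 40 gene lists fixed in advance, 39 had at least 5 measured genes. Markers of stellate cells and fibroblasts had 3 and were not tested. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 78 list tests of both dose comparisons. The lists were tested again with a correlation estimated from the arrays. With that option camera also uses the 6 residual degrees of freedom, which weakens the test by itself. The lists were also tested with fry. It asks whether the genes of a list move on balance in 1 direction, without comparing them with other genes. For each list the count of genes past the threshold is given over all genes tested and adjusted over the list alone. The genes named are the 10 highest and 10 lowest by log2 change among those past the threshold with 1 sign in all 3 same-numbered differences, filled up by the smallest p values where fewer passed, and members of the fixed lists. The difference between doses names 5 per direction. Which of the allowed list members are printed was chosen after their values, and how far these depend on the processing, had been seen, so the printed members are steadier than the whole set. The results of some allowed genes are not reported here.

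The same-numbered arrays were checked for pairing by correlating, across genes, their deviations from the mean of their dose. The r was 0.109 to 0.512 for 0.01 µg/ml and untreated arrays, 0.251 to 0.287 for both treated doses, and 0.0365 to 0.184 for 0.001 µg/ml and untreated arrays. The replicate number was used as a block, fixed or as a random effect, only as an alternative. With it as a fixed block 6036 genes changed at 0.01 µg/ml and 0 at 0.001 µg/ml, and 7683 differed between the doses. Other alternatives were normexp background correction with an offset of 50 together with quantile normalization, quantile normalization alone, median centring, other filters on dim probes, the mean over the probes of a gene, array weights, the slide as a block, the deposited table, other thresholds and test options, the 6 arrays compared alone, and leaving out each array or each replicate number. Without a filter on dim probes a list can also hold its dim members, so its median then covers other genes. The pipeline was tested on simulated data with added log2 changes of 0.5, 1 and 2. At the 0.01 µg/ml comparison it recovered 10.4%, 77.6% and 98.5% of the changed genes and called 3 of 17857 unchanged ones, and it recovered the shifted list with 0 of the 38 others called. At the 0.001 µg/ml comparison it recovered 5.97%, 82.1% and 100% and called 5 unchanged genes. The simulated genes varied independently. The count of lists therefore does not show how camera fares where members are correlated, as in the histone list (estimated correlation 0.66). Tables and plots were made with pandas 2.3.3 and matplotlib 3.10.9 in Python 3.11.15.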

Results

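Gene expression was measured in 9 cultures of HepG2.2.15 cells, 3 at each of 0, 0.001 and 0.01 µg/ml Suduxing, after 48 h. The 3 arrays of a dose correlated across genes with Pearson's r from 0.988 to 0.995. The first principal component held 56.6% of the variance and set the arrays at 0.01 µg/ml, with scores from 49.5 to 57.9, apart from the other 6 arrays, with scores from -32.4 to -24.4. Along the second, which held 15%, scores rose from untreated to 0.01 to 0.001 µg/ml within each replicate number (-30.5, -7.19 and 29.6 for replicate 8, -27.6, -7.12 and -2.31 for replicate 9, and 1.48, 19.2 and 24.4 for replicate 11).

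The first comparison asked which genes Suduxing at 0.01 µg/ml regulated in these cells. IL11, a cytokine of the interleukin-6 family, rose 124-fold (95% interval 99.9 to 155), from a log2 level of -4.39 ± 0.12 (SD, n = 3) relative to the array's 75th percentile in untreated cells to 2.57 ± 0.11 (SD, n = 3). LOXL2, which cross-links collagen, rose 37.1-fold (21.7 to 63.5), the pantetheinase gene VNN1 33.0-fold (25.2 to 43.2) and AQP3, a water and glycerol channel, 30.6-fold (25.4 to 36.9). The largest falls, those of HPR (given below), HAMP and HP, were in plasma protein genes of the liver. HAMP, which encodes the iron-regulating hormone hepcidin, fell 21.8-fold (14.7 to 32.4), from a log2 level of 1.22 ± 0.40 to -3.23 ± 0.09 (SD, n = 3). HP, which encodes the hemoglobin carrier haptoglobin, fell 17.9-fold (14 to 22.9), from 3.39 ± 0.12 to -0.77 ± 0.31 (SD, n = 3). These intervals do not cover the choice of background correction. With normexp and quantile normalization the log2 changes of IL11, VNN1 and HAMP were 5.62, 3.45 and -3.71, against 6.96, 5.04 and -4.45 here. These lay outside the intervals given, whereas that of HP (-3.96, against -4.16) did not.

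The other genes with the largest rises were MMP7, a matrix metalloproteinase, with a log2 change of 4.82 ± 0.41 (SE), AMPD3, an AMP deaminase, with 4.71 ± 0.28, and 4 genes that were not well above background in untreated cells. These were TMEM156 at least 44.7-fold higher, C11orf86 at least 27.1-fold, PRR20B at least 15.6-fold and the phosphodiesterase gene PDE2A at least 14.4-fold. Among the largest falls, HPR, a close relative of HP (signal shared between their probes was not tested), changed by -4.49 ± 0.14, the chemokine gene CXCL2 by -3.55 ± 0.21, the galectin gene LGALS2 by -3.25 ± 0.23 and the myosin gene MYH7B by -3.25 ± 0.22. The glutathione transferase gene GSTA5 was at least 10.9-fold lower, the sterol transporter gene ABCG8 at least 10.2-fold, TBX4 at least 9.30-fold and PAGE4 at least 9.05-fold, since none was well above background at 0.01 µg/ml. The signals of these 4 genes there lay above the floor, so each bound equals the fitted fold. The adjusted p values of these 20 genes were at most 8.45e-05. With normexp background correction and quantile normalization together, all 20 stayed past the threshold, and the log2 changes of 10 of them were smaller by over 1.5 times, such as 3.14 for TMEM156, 3.15 for MMP7 and -1.33 for ABCG8.

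**Figure D1:**
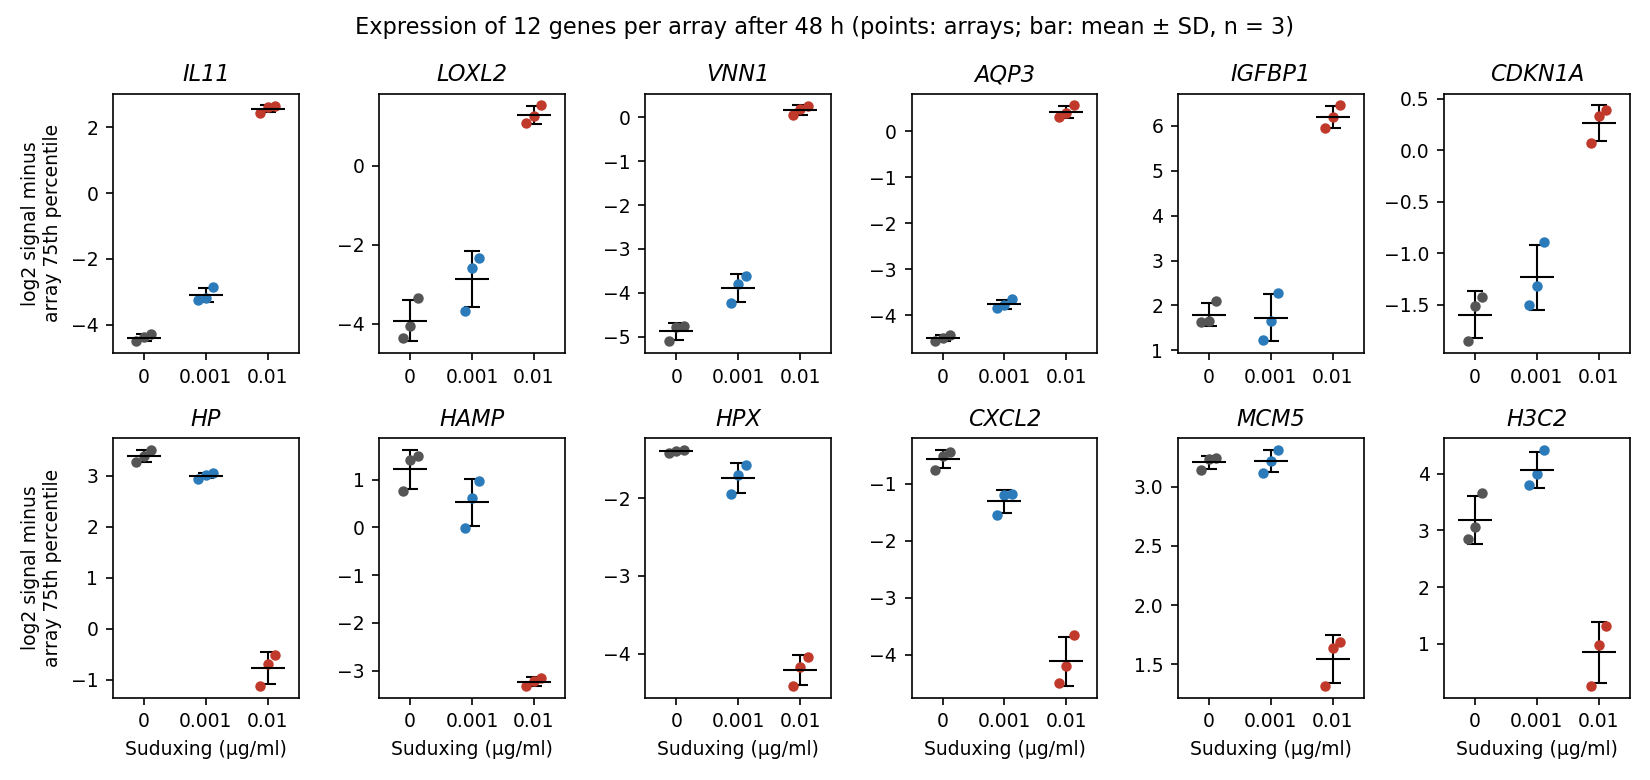
Log2 signal relative to the array's 75th percentile (vertical axes) of 12 genes at 0, 0.001 and 0.01 µg/ml Suduxing (horizontal axes). Points are arrays and bars give the mean and SD of 3 arrays. At 0.01 µg/ml the 3 arrays lay above all others for IL11, LOXL2, VNN1, AQP3, IGFBP1 and CDKN1A and below all others for HP, HAMP, HPX, CXCL2, MCM5 and H3C2.

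In all, 4670 of 18080 genes changed at 0.01 µg/ml, 2222 upward and 2448 downward. Of these, 907 were at least 2-fold higher and 471 at least 2-fold lower, and 255 and 70 passed 4-fold. The split by direction depended on the scaling. After median centring 1940 genes rose and 2752 fell, and with normexp and quantile normalization 2308 rose and 2298 fell. Among 823 changed genes with several probes, another probe was called in the same direction for 491 and in the opposite direction for 7. Without replicate 8, 9 or 11 at every dose, which leaves 2 arrays per dose, 2569, 2021 and 2954 genes passed, and without a filter on dim probes 2700 passed.

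The lists of p53 targets and of cell division genes pointed in opposite directions. Of 25 measured p53 targets, 20 rose and 0 fell (23 and 0 adjusted over the list alone), among them the cell cycle inhibitor CDKN1A with a log2 change of 1.86 ± 0.19, the death receptor FAS with 1.86 ± 0.17, PLK3 with 1.34 ± 0.14, MDM2, which encodes the ligase that degrades p53, with 1.17 ± 0.12, and GDF15 with 1.38 ± 0.22. The list had a median of 0.86 and camera adjusted p = 1.57e-13, and it was the only list of the 39 that passed at this dose with an estimated correlation as well (adjusted p = 0.0174 with an estimated correlation). Of 26 S phase genes, 21 fell and 0 rose (24 and 0 adjusted over the list alone; median -0.67, adjusted p = 2.16e-09), but adjusted p = 0.0917 with an estimated correlation. They included the replicative helicase subunits MCM5 (-1.66 ± 0.13) and MCM2 (-0.95 ± 0.13) and the helicase partner GINS2 (-1.12 ± 0.11). Of 24 mitotic genes, 20 fell (22 adjusted over the list alone; median -0.73, adjusted p = 2.16e-09), with adjusted p = 0.128 with an estimated correlation. MKI67 changed by -1.34 ± 0.17, the cyclins CCNA2 by -1.09 ± 0.14 and CCNB1 by -1.04 ± 0.13, and the spindle checkpoint kinase BUB1 by -0.98 ± 0.13. Of 26 replication-dependent histone genes, 25 fell (25 adjusted over the list alone; median -1.27, adjusted p = 9.02e-11), with adjusted p = 0.304 with an estimated correlation. Examples are H1-5 (-2.45 ± 0.20, or -1.49 with normexp and quantile normalization), H3C10 (-2.34 ± 0.28), H3C2 (-2.33 ± 0.29) and H2BC3 (-2.07 ± 0.29). Of 27 apoptosis regulators, 9 rose and 3 fell (13 and 4 adjusted over the list alone; median 0.40, adjusted p = 0.0137), with adjusted p = 0.146 with an estimated correlation. Both promoters and inhibitors of cell death moved: the pro-apoptotic genes PMAIP1 (2.71 ± 0.15), HRK (1.30 ± 0.15) and BBC3 (0.75 ± 0.12) rose with the anti-apoptotic MCL1 (1.04 ± 0.17), and the survivin gene BIRC5 fell (-0.81 ± 0.13).

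Lists of immediate early, hypoxia, amino acid response, aryl hydrocarbon receptor and metallothionein genes pointed upward and passed. NRF2 targets (5 of 21 rose and 4 fell, 5 and 5 adjusted over the list alone; adjusted p = 0.449) and drug metabolism genes (5 of 12 rose and 3 fell, 5 and 3 adjusted over the list alone; adjusted p = 0.33) did not pass. Of 26 immediate early genes, which respond quickly to growth factors and stress, 17 rose and 0 fell (18 and 0 adjusted over the list alone; median 0.81, adjusted p = 2.16e-09), with adjusted p = 0.0538 with an estimated correlation. The phosphatase gene DUSP5 rose by 4.32 ± 0.20, EGR1 by 2.01 ± 0.13 and CCN1 by 1.68 ± 0.14. Of 25 hypoxia and glycolysis genes, 15 rose and 0 fell (15 and 0 adjusted over the list alone; median 0.48, adjusted p = 7.85e-07), with adjusted p = 0.146 with an estimated correlation. They included ADM (2.01 ± 0.27), NDRG1 (1.97 ± 0.24) and the glucose transporter SLC2A1 (1.06 ± 0.14). Of 22 amino acid response and ATF4 targets, 13 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.64, adjusted p = 1.56e-06), with adjusted p = 0.139 with an estimated correlation. The cystine transporter SLC7A11 rose by 2.06 ± 0.16, the asparagine synthetase ASNS by 1.30 ± 0.17, ATF3 by 1.17 ± 0.12 and CBS by 1.07 ± 0.16. Of 5 measured aryl hydrocarbon receptor targets, 4 rose (4 adjusted over the list alone; median 1.37, adjusted p = 0.000133), with adjusted p = 0.112 with an estimated correlation. The cytochrome CYP1A1 rose by 4.01 ± 0.18, CYP1A2 by 2.08 ± 0.25 (0.997 with normexp and quantile normalization), NQO1 by 1.37 ± 0.22 and UGT1A6 by 0.99 ± 0.14. Of 11 genes on the metallothionein list, 8 rose and 2 fell (8 and 2 adjusted over the list alone; median 2.31, adjusted p = 1.75e-05), with adjusted p = 0.325 with an estimated correlation. Metallothioneins are small metal-binding proteins, and the list also holds the zinc transporter gene SLC30A1. MT1M (2.62 ± 0.20, or 1.47 with normexp and quantile normalization), MT1H (2.37 ± 0.20), MT1B (2.31 ± 0.21) and MT2A (2.10 ± 0.17) rose, whereas MT1G (-1.70 ± 0.28, or -0.68 with normexp and quantile normalization) and MT1F (-0.67 ± 0.22) fell. Signal shared between the probes of these similar genes was not tested, so the rises may not be separate. The call of MT1F ended without any 1 of untreated replicates 8 and 9, replicates 8, 9 and 11 at 0.01 µg/ml or replicate 9 at 0.001 µg/ml, with adjusted p from 0.0611 to 0.157. It also ended after quantile normalization (adjusted p = 0.0503), with the deposited table (0.0503) and without a filter on dim probes (0.163). With normexp and quantile normalization MT1F changed by -0.39 (adjusted p = 0.0266).

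The list of cholesterol biosynthesis pointed upward, and those of chaperones, nucleotide metabolism and ribosomes downward, the latter with few members past the threshold. Of 23 cholesterol biosynthesis genes, 15 rose and 0 fell (17 and 1 adjusted over the list alone; median 0.58, adjusted p = 9.97e-07), with adjusted p = 0.128 with an estimated correlation. MSMO1 rose by 1.23 ± 0.22 and HSD17B7 by 0.75 ± 0.12. Of 19 genes of the unfolded protein response, 7 fell and 0 rose (8 and 0 adjusted over the list alone; median -0.43, adjusted p = 0.00231), with adjusted p = 0.146 with an estimated correlation. The ER chaperone HSPA5 fell by 1.72, SDF2L1 by 1.25 and CRELD2 by 1.03 on the log2 scale. Of 17 heat shock protein genes, 9 fell and 2 rose (12 and 3 adjusted over the list alone; median -0.50, adjusted p = 0.0185), with adjusted p = 0.146 with an estimated correlation, or adjusted p = 0.0505 after quantile normalization. HSPA1A (-1.24 ± 0.12) and HSPA8 (-0.80 ± 0.13) fell, whereas the small heat shock proteins CRYAB (2.17 ± 0.13) and HSPB8 (1.15 ± 0.15) rose. Of 20 genes of nucleotide and one-carbon metabolism, 10 fell and 0 rose (12 and 0 adjusted over the list alone; median -0.37, adjusted p = 0.00522), with adjusted p = 0.146 with an estimated correlation, among them MAT2A (-0.80 ± 0.13) and CTPS1 (-0.72 ± 0.12). Of 32 cytosolic ribosomal protein genes, 7 fell and 0 rose (5 and 0 adjusted over the list alone; median -0.26, adjusted p = 0.00331), with adjusted p = 0.518 with an estimated correlation. That median was -0.09 after quantile normalization (adjusted p = 0.198). Of 26 ribosome biogenesis genes and MYC targets, 4 fell and 0 rose (2 and 0 adjusted over the list alone; median -0.20, adjusted p = 0.0469), with adjusted p = 0.364 with an estimated correlation. This call ended without untreated replicate 8 (adjusted p = 0.125) or 9 (0.067) and without replicate 8 (0.0607) or 11 (0.131) at 0.01 µg/ml. It also ended after quantile normalization (median -0.13, adjusted p = 0.155), with normexp and quantile normalization (-0.12, 0.104), with the deposited table (-0.13, 0.157), after median centring (0.0551), with the mean over the probes of a gene (0.0649) and with probes well above background on all 9 arrays (0.061).

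Lists of proteins that hepatocytes secrete pointed downward, whereas the list of liver transcription factors did not pass. Of 18 genes of hepatocyte secreted proteins, 11 fell and 0 rose (12 and 1 adjusted over the list alone; median -0.62, adjusted p = 1.25e-05), with adjusted p = 0.146 with an estimated correlation. The heme carrier HPX changed by -2.81 ± 0.14 (-1.85 with normexp and quantile normalization), the fibrinogen gene FGG by -1.70 ± 0.16, APOH by -1.63 ± 0.16 and the HDL protein APOA1 by -1.38 ± 0.15. Of 13 acute phase protein genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.76, adjusted p = 0.000376), with adjusted p = 0.0917 with an estimated correlation. Besides HAMP and HP, ORM1 (-1.69 ± 0.10) and ORM2 (-1.65 ± 0.11) fell, while CP, which encodes the copper carrier ceruloplasmin, rose (2.32 ± 0.17), and the median was -0.32 with normexp and quantile normalization. Of 19 complement and coagulation genes, 11 fell and 2 rose (11 and 2 adjusted over the list alone; median -0.55, adjusted p = 0.000203), with adjusted p = 0.18 with an estimated correlation. Kininogen KNG1 changed by -2.67 ± 0.13, C1S by -1.35 ± 0.12 and CFB by -1.28 ± 0.17, and without a filter on dim probes the median was -0.37. Of 19 liver transcription factors and nuclear receptors, 8 fell and 2 rose (8 and 3 adjusted over the list alone), and the list did not pass (median -0.23, adjusted p = 0.135). The bile acid receptor NR1H4 changed by -2.37 ± 0.16, RXRA by -0.91 ± 0.12 and the xenobiotic receptor NR1I2 by 0.84 ± 0.13. Of 7 measured markers of endothelial cells, which these cultures should not hold, 5 rose and 0 fell (5 and 0 adjusted over the list alone; median 2.41, adjusted p = 0.000155), with adjusted p = 0.146 with an estimated correlation. ESAM rose by 3.08 ± 0.21, LYVE1 by 3.40 ± 0.20 (1.62 with normexp and quantile normalization) and VWF by 2.41 ± 0.18 (1.28 with normexp and quantile normalization), TIE1 was at least 2.96-fold higher, and PECAM1 rose by 0.997 ± 0.311. The list's median was 1.57 with TIE1 at its bound and 0.69 with normexp and quantile normalization. It was 0.04 without a filter on dim probes, where the list also holds markers that are dim at every dose. The call of PECAM1 ended without untreated replicate 9 or 11 or without replicate 8 or 9 at 0.01 µg/ml, with adjusted p from 0.0868 to 0.13, and with normexp and quantile normalization (0.33, adjusted p = 0.0508).

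**Figure D2:**
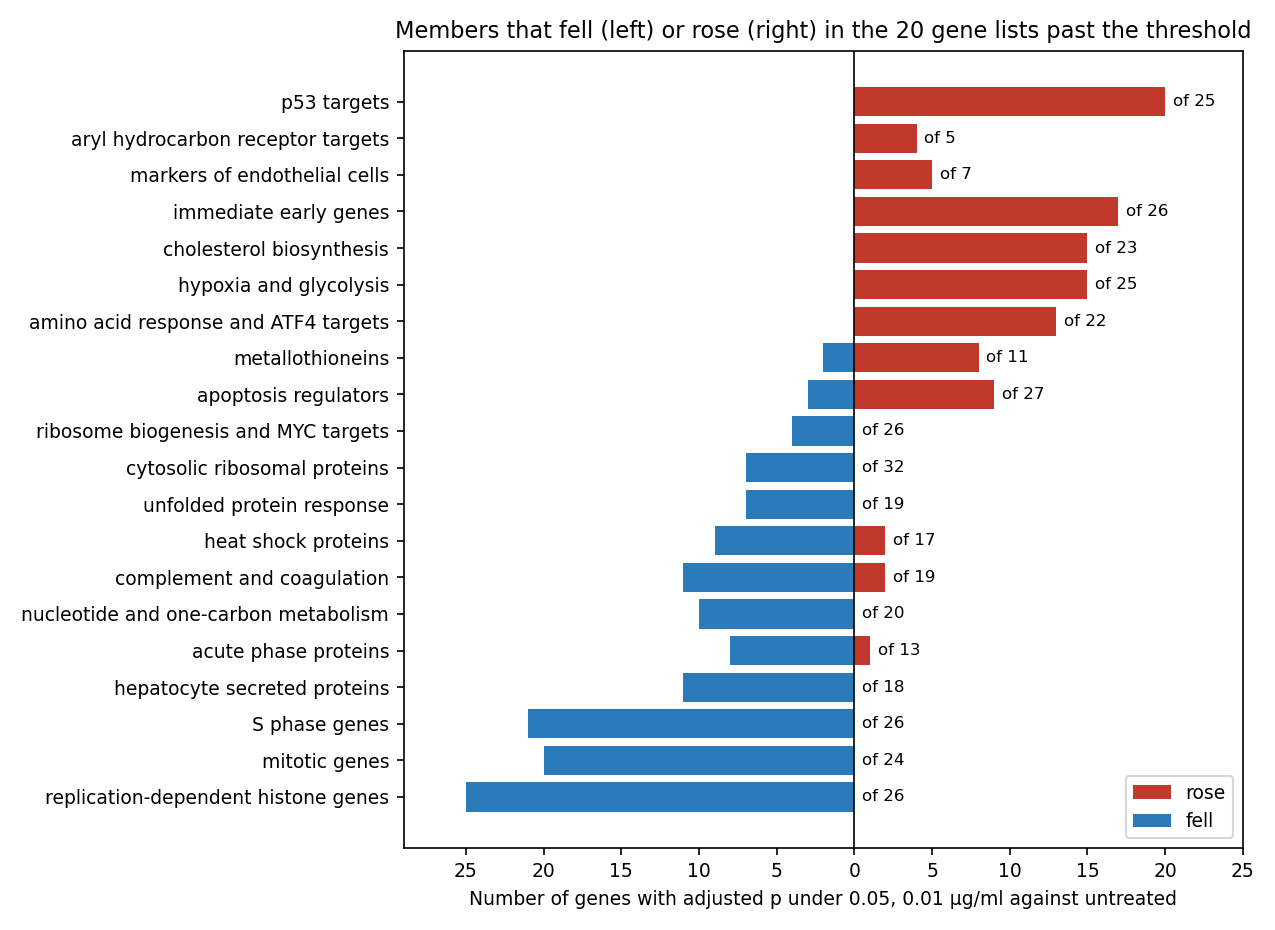
Numbers of genes (horizontal axis) that fell (left, blue) or rose (right, red) at 0.01 µg/ml against untreated cells in each of the 20 gene lists that passed the test with the preset correlation, with the number of measured genes beside each bar. p53 targets had the most rises, 20 of 25, and replication-dependent histone genes the most falls, 25 of 26.

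In all, 20 of 39 lists passed at 0.01 µg/ml with the preset correlation, 9 toward higher and 11 toward lower expression, whereas 1 passed with an estimated correlation and 33 with fry. Lists of host factors of the virus and of immune genes did not pass, and no list held genes of the virus itself. Of 20 hepatitis B virus host factors, 2 rose and 3 fell (2 and 3 adjusted over the list alone; adjusted p = 0.61), among them the receptor EGFR (0.83 ± 0.11) and the flap endonuclease FEN1 (-0.99 ± 0.14). Of 18 interferon-stimulated genes, 5 rose and 5 fell (6 and 5 adjusted over the list alone; adjusted p = 0.426), such as OAS1 (1.27 ± 0.10) and the RNA sensor IFIH1 (-1.56 ± 0.16). That list's median was -0.15 while its mean was 0.11 and its test pointed upward. Of 14 NF-kB and inflammatory targets, 7 rose and 3 fell (7 and 4 adjusted over the list alone; adjusted p = 0.218). CCL20 (1.90 ± 0.16) and IER3 (1.20 ± 0.13) rose, while CXCL2 was among the largest falls.

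The second comparison asked the same of 0.001 µg/ml. No gene passed with limma (0 of 18080), although 2716 genes had an unadjusted p under 0.05 where 904 would be expected by chance. IL11 had the smallest adjusted p, at 2.45-fold (95% interval 1.97 to 3.05; adjusted p = 0.0671), from -4.39 ± 0.12 to -3.10 ± 0.22 (SD, n = 3). The next genes above the untreated level were RASSF2, a Ras-binding protein, with a log2 change of 1.15 ± 0.15 and adjusted p = 0.115, and then OR5L2 (1.01 ± 0.16), TLCD3B (0.97 ± 0.16), NEK7 (0.86 ± 0.14), AQP3 (0.74 ± 0.12), VNN1 (0.99 ± 0.17), TM4SF1 (0.60 ± 0.11), INHBB (0.65 ± 0.12) and SYNGR4 (0.90 ± 0.16), each with adjusted p = 0.177. Below it were FBLN5 (-0.68 ± 0.12) with adjusted p = 0.177 and ZNF211 (-0.60 ± 0.12), EMC4 (-0.60 ± 0.12), AGXT (-0.62 ± 0.13), SLC6A14 (-0.92 ± 0.20), CRYBG1 (-0.58 ± 0.12), TBC1D7 (-0.61 ± 0.13), YY1AP1 (-0.48 ± 0.11), XAF1 (-0.52 ± 0.12) and VXN (-0.75 ± 0.18), each with adjusted p = 0.21. None of these 20 passed. At 0.01 µg/ml, 15 of the 20 passed, where 4670 of all 18080 genes did. Of the 15, 13 moved in the same direction and 2, NEK7 (-0.51 ± 0.14) and ZNF211 (0.46 ± 0.12), in the opposite one. The 20 were picked by small p values, and both comparisons use 1 estimate of each gene's spread. Genes with a small spread therefore pass more readily in both. Both doses were also compared with the same untreated arrays, so some of this agreement is expected without any effect at 0.001 µg/ml. Simulated doses with no effect gave the same sign in 66.7% of all genes, and 53.7% of all genes measured had the same sign. The simulation left out the effect at 0.01 µg/ml. It also left out the medians of all genes, which were -0.07 at 0.01 µg/ml and 0.08 at 0.001 µg/ml. These shares therefore cannot tell how far the doses agree. With normexp and quantile normalization the log2 changes of 11 of the 20 were smaller by over 1.5 times, such as 0.57 for IL11. With the replicate number as a random effect 11 genes passed, IL11 (adjusted p = 0.0104) and RASSF2 (0.0217) among them, whereas 0 passed with it as a fixed block, and with at least 2-fold and an unadjusted p under 0.05 there were 91.

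At 0.001 µg/ml, 13 of 39 lists passed with the preset correlation, 0 with an estimated one and 8 with fry, and 0 members passed over all genes in any of them. The 26 replication-dependent histone genes all had positive log2 changes (1 rose adjusted over the list alone; median 0.60, adjusted p = 8.89e-08), with adjusted p = 0.364 with an estimated correlation. That median was 0.37 without replicate 8 at 0.001 µg/ml and 0.39 after median centring. Genes of acute phase proteins (0 rose and 1 fell adjusted over the list alone; median -0.31, adjusted p = 0.000207; adjusted p = 0.0917 with an estimated correlation) and of complement and coagulation (0 and 0 adjusted over the list alone; median -0.22, adjusted p = 0.000133; adjusted p = 0.169 with an estimated correlation) lay below the untreated level. The acute phase median was -0.20 without replicate 11 at 0.001 µg/ml. The acute phase median was -0.52 after median centring and -0.10 without a filter on dim probes, and the complement median -0.43 and -0.13. With camera's preset correlation these 3 lists passed under every processing alternative and with every array left out, but with fry only the acute phase list did (adjusted p = 0.0072, against 0.0879 for histones and 0.0679 for complement).

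The other 10 lists that passed at 0.001 µg/ml lost their call under at least 1 alternative. Relative to the median of all genes, which was 0.08 at this dose and -0.14 after median centring, the medians were -0.25 for metallothioneins (2 fell adjusted over the list alone; adjusted p = 0.00579, and adjusted p = 0.433 with an estimated correlation), -0.14 for immediate early genes (adjusted p = 0.00579, and adjusted p = 0.146 with an estimated correlation) and -0.19 for interferon-stimulated genes (adjusted p = 0.00833, and adjusted p = 0.153 with an estimated correlation). They were -0.14 for nucleotide and one-carbon metabolism (adjusted p = 0.00961, and adjusted p = 0.146 with an estimated correlation), -0.21 for hepatocyte secreted proteins (adjusted p = 0.0171, and adjusted p = 0.325 with an estimated correlation), -0.18 for mitotic genes (adjusted p = 0.0185, and adjusted p = 0.385 with an estimated correlation) and -0.17 for liver transcription factors and nuclear receptors (adjusted p = 0.0208, and adjusted p = 0.146 with an estimated correlation). They were 0.12 for NRF2 targets (1 rose adjusted over the list alone; adjusted p = 0.0273, and adjusted p = 0.25 with an estimated correlation), -0.10 for NF-kB targets (adjusted p = 0.0335, and adjusted p = 0.152 with an estimated correlation) and -0.21 for bile acid genes (adjusted p = 0.0372, and adjusted p = 0.158 with an estimated correlation). In the lists without a count here, 0 members passed adjusted over the list alone. Without replicate 11 at 0.001 µg/ml, 7 lists passed. That array, the other arrays at this dose and those of the untreated cells each ended some of these 10 calls when left out, with adjusted p of at most 0.181 for a single array. Medians against untreated cells, here not relative to all genes, moved as well. That of metallothioneins (-0.17) was -0.05 without untreated replicate 8 and -0.04 and -0.30 without replicates 11 and 8 at 0.001 µg/ml, and that of mitotic genes (-0.10) was -0.02 and -0.18 without replicates 11 and 9 at that dose. Hepatocyte secreted proteins (-0.14) had -0.06 and -0.21 without untreated replicates 8 and 11, interferon-stimulated genes (-0.12) -0.17 and -0.07, and liver transcription factors (-0.09) -0.06 without untreated replicate 8. Immediate early genes (-0.06) had -0.04, -0.01 and -0.16 without untreated replicates 8, 9 and 11 and -0.11 without replicate 8 at 0.001 µg/ml. One-carbon genes (-0.06) had -0.11 without untreated replicate 8 and -0.09 without replicate 9 at 0.001 µg/ml, and NF-kB targets (-0.03) had -0.09 without untreated replicate 8 or 9 and -0.05 and -0.02 without replicates 8 and 9 at 0.001 µg/ml. Without a filter on dim probes the medians of bile acid genes (0.10) and NF-kB targets (0.03) were positive, and after median centring that of NRF2 targets was negative (-0.01).

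The third comparison tested the difference between both doses directly. The genes with the largest differences were those of the first comparison and a few others: IL11 was 50.8-fold (95% interval 40.7 to 63.2) higher at 0.01 than at 0.001 µg/ml, IGFBP1, which encodes an insulin-like growth factor binding protein, 22.3-fold (15.1 to 33.1), and DUSP5 18.7-fold (13.8 to 25.3). TMEM156 was at least 29.4-fold and C11orf86 at least 20.2-fold higher. Lower at 0.01 µg/ml were HPR by 15.4-fold (12.4 to 19.1), HP by 13.7-fold, HAMP by 13.5-fold (9.09 to 20.1), LGALS2 by 9.58-fold (6.69 to 13.7) and H3C2 by 9.32-fold (5.93 to 14.6), and the adjusted p of these 10 genes was at most 4.77e-05. With normexp and quantile normalization the log2 differences of TMEM156 and C11orf86 were 3.11 and 2.42, and with the mean over its probes that of C11orf86 was 2.86, against 6.01 and 4.87 here. Those of IL11 and HAMP were 5.04 and -3.03 with normexp and quantile normalization, against 5.67 and -3.755 here, outside the intervals given as folds. That of HP was -3.55, against -3.77. In all, 6092 genes differed, 2208 higher and 3884 lower at 0.01 µg/ml, and 5585 differed between any of the 3 doses by the moderated F-test. The latter count was 3669 without replicate 8 and 3436 without replicate 9 at 0.01 µg/ml, and 2091, 1890 and 3701 without replicate 8, 9 or 11 at every dose.

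The share of differing genes that were higher at 0.01 µg/ml depended on the scaling. It was 36.2% here, where the median of all genes was -0.15, and 51.8% after quantile normalization, 53.1% with normexp added to quantile normalization and 59.2% after median centring, where that median was 0.02. Without replicate 9 at 0.01 µg/ml 3930 genes differed, and without replicate 8 or 9 at every dose 2529 and 2465. Of 39 lists, 22 passed, 12 toward higher and 10 toward lower expression at 0.01 µg/ml, and 2 of them held with an estimated correlation. These were p53 targets (22 of 25 higher, 22 adjusted over the list alone; median 0.91; adjusted p = 0.00669 with an estimated correlation) and immediate early genes (17 of 26 higher, 17 adjusted over the list alone; median 0.90; adjusted p = 0.012 with an estimated correlation). All 26 histone genes were lower (26 adjusted over the list alone; median -1.95, adjusted p = 2.27e-13), with adjusted p = 0.182 with an estimated correlation.

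**Figure D3:**
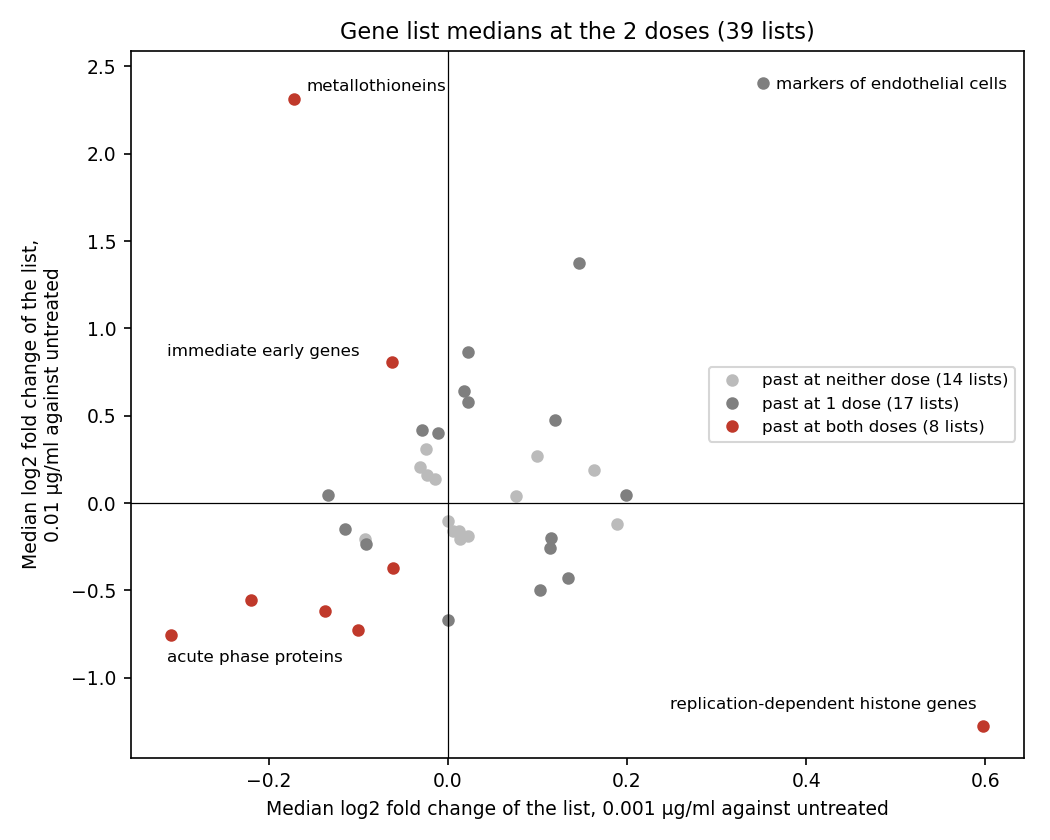
Median log2 fold change of each of 39 gene lists at 0.001 µg/ml (horizontal axis) and 0.01 µg/ml (vertical axis) against untreated cells, with 1 point per list. Red lists (8) passed the test with the preset correlation at both doses, dark grey (17) at 1 dose and light grey (14) at neither. Acute phase proteins lay below 0 at both doses (-0.31 and -0.76), whereas replication-dependent histone genes lay above 0 at 0.001 µg/ml (0.60) and below it at 0.01 µg/ml (-1.27).

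The last comparison set the effects of both doses side by side. Across the 18080 genes, which are not independent replicates, the log2 changes at both doses correlated with Pearson's r = 0.226 and Spearman's rho = 0.191, and their covariance was 0.042. Both changes were taken against the same 3 untreated arrays, which by itself gives a correlation: simulated doses without any effect gave r = 0.5 and a covariance of 0.02. The simulation left out the effect at 0.01 µg/ml, so its r is no reference for the measured r. The measured covariance exceeded the simulated one by 0.022, but the simulation drew all arrays independently and so left out the correlation of same-numbered arrays. With 3 untreated arrays no 2 sets of at least 2 can be made, so part of the correlation may come from the shared arrays. The r was 0.307 without untreated replicate 11 and 0.158 without replicate 11 at 0.01 µg/ml.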

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

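The comparison of histone genes with S phase genes was chosen only after the result was seen. The lists of histones, metallothioneins and immediate early genes passed at both doses with the preset correlation and had medians of opposite sign. At 0.001 µg/ml 0 members of these lists passed over all genes, and with an estimated correlation the lists had adjusted p = 0.364, 0.433 and 0.146 there. With fry they had adjusted p = 0.0879, 0.404 and 0.0979. The call of metallothioneins at 0.001 µg/ml ended without untreated replicate 8 (adjusted p = 0.0596) or replicate 11 at 0.001 µg/ml (0.138), and that of immediate early genes without replicate 8 at every dose (0.0643). Metallothioneins had a median log2 difference of 2.30 between 0.01 and 0.001 µg/ml (adjusted p = 2.38e-08), with medians of 2.31 and -0.17 against untreated cells, but adjusted p = 0.169 with an estimated correlation. Immediate early genes had a median difference of 0.90 (adjusted p = 9.13e-13), with medians of 0.81 and -0.06, and adjusted p = 0.012 with an estimated correlation. Replication-dependent histone genes had a median difference of -1.95 (adjusted p = 2.27e-13), with medians of -1.27 and 0.60, but adjusted p = 0.182 with an estimated correlation.

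On average, the histone genes lay above untreated cells at 0.001 µg/ml and below them at 0.01 µg/ml. Each array at 0.001 µg/ml lay above the untreated array of its number, but the groups overlapped. The histone mean was 1.59 in replicate 9 at 0.001 µg/ml and 1.63 in untreated replicate 11. Array brightness was tested as a cause. Its slope within doses predicted a mean shift of 0.0932 (95% interval -0.0637 to 0.25) at 0.001 µg/ml, where 0.618 was seen. At 0.01 µg/ml it predicted -0.189 (-0.507 to 0.129), where -1.39 was seen. These intervals hold the error of the slope only, not the spread of the observed shifts over 3 arrays per dose. The dimmest array, replicate 8 at 0.001 µg/ml, also had the highest histone mean (2.35). Brightness is therefore not excluded at 0.001 µg/ml, where the groups overlapped. A smaller share of cells in S phase could explain the fall at 0.01 µg/ml, where S phase genes had a median of -0.667, but perhaps not all of it, since the histone median of -1.27 lay 1.84 SD of the S phase genes below theirs (-1.84). At 0.001 µg/ml the S phase genes had a median of 0.0002, and the histone median lay 2.79 SD of the S phase genes above theirs. This SD is the spread of changes over S phase genes, not an error of either median. Whether both lists respond alike to the share of cells in S phase was not tested, so that share is not excluded. Signal shared between the probes of similar histone genes was not tested and remains open.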

How the results depend on the processing

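At 0.01 µg/ml, 4670 genes changed, 2700 without a filter on dim probes and 1417 with an unadjusted p under 0.05 and at least 2-fold. Leaving arrays out gave 2021 (without replicate 9) to 4918 (without replicate 8 at 0.001 µg/ml). At 0.001 µg/ml, 0 genes changed, 1 with probes well above background on all 9 arrays, 11 with the replicate number as a random effect (0 with it as a fixed block), 1 with the slide as a block (the same as leaving out untreated replicate 11, which was alone on its slide), 1 at adjusted p under 0.10, 91 with an unadjusted p under 0.05 and at least 2-fold, and 1 with trend and robust options. Leaving arrays out gave 0 to 1, the latter without untreated replicate 11. Between the doses 6092 genes differed, 1555 with an unadjusted p under 0.05 and at least 2-fold, and 2465 (without replicate 9) to 6089 (without untreated replicate 11). Between any doses 5585 differed, 3178 without a filter, and 1890 (without replicate 9) to 5908 (without replicate 9 at 0.001 µg/ml).

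At 0.01 µg/ml 20 lists passed, 1 with an estimated correlation and 33 with fry. At 0.001 µg/ml 13 passed, 8 after quantile normalization, 21 without a filter, 8 with the deposited table, 0 with an estimated correlation, 8 with fry, and 7 (without replicate 11 at 0.001 µg/ml) to 13 with arrays left out. The r of the dose effects was 0.226, 0.176 with normexp and quantile normalization, 0.166 with quantile normalization alone, 0.171 without a filter, 0.288 with array weights, 0.164 with the deposited table, and 0.158 (without replicate 11 at 0.01 µg/ml) to 0.307 (without untreated replicate 11, the same as the slide as a block).

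Over the alternatives of processing, blocks, array weights and arrays left out, calls of the 106 genes printed at 0.01 µg/ml stayed in 2399 of 2419 results. Those genes were picked after this was seen. Over all 381 genes that the naming rules allowed, the calls stayed in 7643 of 8729, were lost in 1064, gained in 15 and changed sign in 7. For lists they stayed in 442 of 458 at 0.01 µg/ml and in 244 of 299 at 0.001 µg/ml, all with camera's preset correlation. These counts leave out fry and the estimated correlation. With the latter, 19 of 20 list calls were lost at 0.01 µg/ml and 13 of 13 at 0.001 µg/ml. Correlation between members is not the only reason, since camera then also uses the 6 residual degrees of freedom. Acute phase genes had an estimated correlation of -0.016, below the preset 0.01. Even so, their unadjusted camera p at 0.01 µg/ml went from 8.19e-05 to 0.00588.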

Other observations

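The tests of endothelial markers and of RNA carried over between cultures were chosen only after the result was seen. Some genes were well above background in treated cells and not in untreated cells, or the reverse. On all 3 arrays at 0.01 µg/ml and on no untreated array were 188 genes, 161 of them called higher, and the reverse held for 62 genes, 58 of them called lower. On all 3 arrays at 0.001 µg/ml and no untreated array there were 3, and the reverse held for 78, with 0 genes called at this dose. Fewer spots were well above background on replicates 8 and 11 at 0.001 µg/ml (54.1% and 54.3%) than on the untreated arrays (56.0% to 59.0%), so these 78 are no evidence of lost expression.

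Amino acid and lipid genes moved in both directions at 0.01 µg/ml without their lists passing. Of 15 genes of the urea cycle and amino acid catabolism, 5 rose and 6 fell (6 and 6 adjusted over the list alone; adjusted p = 0.99), such as NAGS (log2 change 2.06), AGXT (-1.33) and TDO2 (-2.85, or -1.37 with normexp and quantile normalization). Of 17 genes of fatty acid and triglyceride synthesis, 2 rose and 4 fell (7 and 5 adjusted over the list alone; adjusted p = 0.506), such as LPIN1 (1.51), DGAT1 (-1.37) and GPAM (-1.32). Its median was 0.14, its mean -0.0016, and its test pointed upward. Of 10 markers of immune cells, 4 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.121), with CD3D at 3.30, CD163 at 1.11 and CD14 at -2.23.

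Of 7 measured markers of endothelial cells, 5 rose at 0.01 µg/ml (5 adjusted over the list alone), with adjusted p = 0.146 for the list with an estimated correlation. Cells of another type in the cultures would bring markers that untreated cells lack. Of 7 such markers, 6 were not well above background on any array at 0.01 µg/ml. VIM was not well above background on any of the 9 arrays. However, no array here shows that the probes of VIM and of these 6 markers can detect them. Cells of another type are therefore not excluded. Whether dim probes were the cause stays open for the list as a whole. All 5 markers that rose were well above background on all 3 arrays at 0.01 µg/ml, but the filter on dim probes kept TIE1, LYVE1 and PECAM1 only for that reason. It did not for ESAM and VWF, which were well above background on all 3 untreated arrays too. Without the filter the list's median was 0.04, but the list then also held markers dim at every dose, such as KDR and FLT1. It still passed camera with the preset correlation (adjusted p = 0.000692).

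The changes at 0.001 µg/ml leaned toward those at 0.01 µg/ml. Genes were chosen against 2 untreated arrays and measured against the third, and the median change of all genes was then subtracted. The median change in the direction of 0.01 µg/ml was at least 0.103 in 3 of 3 rotations (mean 0.13, SE 0.0143 over rotations), which speaks against the shared untreated arrays as the whole cause. Its excess over unchanged genes of the same signal level was at least 0.0818 (mean 0.102, SE 0.0111). All rotations used the same arrays at 0.001 and 0.01 µg/ml, so neither SE measures the spread between cultures. Genes lower at 0.01 µg/ml had a median change of -0.0743 in the rotation with the smallest fall. The share of carried-over RNA that IL11 sets gave -0.0102. The first value is relative to the median of all genes, which was 0.0754 at 0.001 µg/ml in the main fit. The second is not, so the pair cannot tell whether carried-over RNA accounts for the fall. A weak effect of the same kind at 0.001 µg/ml is consistent with these values, yet 0 genes passed there.

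Regrouping the arrays asked how often other groups give as many calls. With 10 splits of 6 arrays a share under 1 in 20 cannot be reached, so only the counts are given. At 0.01 µg/ml 1 of 10 splits, the real 1, gave as many genes (4670, highest other 0) and lists (20, highest other 18), and between the doses 1 of 10 gave as many genes (6092, highest other 0). At 0.001 µg/ml 1 of 10 gave as many lists (13, highest other 7), and since the real count of genes was 0, 10 of 10 had to give as many, which says nothing. The other splits set arrays of both doses 2 to 1 against each other, so they keep part of any effect. For genes differing between any doses, 1 of 100 splits of 9 arrays, the real 1, gave as many (5585, highest other 3960), which argues against an accident of grouping, and both other splits with any calls kept the 0.01 µg/ml arrays together.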
